A study of Mus musculus with 20 samples.

How the data were processed

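RNA of frozen left ventricle from 20 male mice was profiled in 4 groups of 5, WT and iKO on chow and on HFD. Per the labels' protocols, total RNA with an integrity number above 8 was made into poly(A)-enriched TruSeq libraries and sequenced on a HiSeq instrument as 100 nt single-end reads, at a stated depth of about 50 M reads. Tamoxifen (20 mg/kg for 5 days at 8 weeks of age) was given to both genotypes, per the labels' protocols. The groups come from the genotype and diet in the labels, and library names RT1 to RT20 are those of the labels. No group with the Cre and without floxed alleles is among the samples, so that effects of ACC2 loss cannot be told apart from effects of the Cre transgene or of its insertion.

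The deposited values are FPKM per gene, printed to 2 decimals, 1 table per library, as made by the authors. The submitters' processing notes name Bowtie2, RSEM and DESeq2 without versions and the genome build mm9. The tables list 25052 genes, each above 0 in at least 1 of the 20 libraries, and hold no coordinates. Of their versioned Ensembl IDs 24938 are in GENCODE M21, an annotation of GRCm38, 19995 of them with the same version. This conflicts with the stated mm9, and coordinates are given on GRCm38 by ID. The genes were matched by ID, because 70 IDs share their symbol with another ID. No 2 libraries were identical, and the correlation of log2 values between libraries lay between 0.983 and 0.995. The remaining columns hold gene and transcript IDs and the symbol.

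FPKM are not counts, so the quasi-likelihood count test chosen beforehand was not run, and its stated fallback was used. Values were taken as log2(FPKM + 1), which understates the change of genes with low values, and genes were kept with at least 0.5 FPKM in at least 5 libraries, which left 12775. This minimum was set once the unit was known and before any comparison was run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. Limma with an intensity trend and robust variance moderation was fitted to all 20 libraries with 4 group means, and each of 4 pairwise contrasts and the interaction was adjusted by Benjamini-Hochberg over all genes tested, with calls at 0.05. Errors of fold changes are limma's SE and errors of FPKM are SDs over the 5 mice of a group. Tested on simulated data, drawn for each gene independently from its mean and residual SD with 50 genes changed at each size, the fit recovered 94% of changes of 1.5-fold on chow, 90% on HFD, 80% between diets in WT and 88% between diets in iKO, and at 1.25-fold 58%, 42%, 62% and 56%. In these simulations 4.4%, 5.2%, 3.4% and 5% of the calls were false. The changed genes had a mean log2 value of at least 1, and the change was added on the log2(FPKM + 1) scale. Recovery of genes with lower values was not simulated.

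The comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Of 39 gene lists, 34 had at least 5 tested members and were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 34 lists. Camera with an estimated correlation and the directional test of fry were run beside it. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. The called lists numbered 16 on chow, 20 on HFD, 14 for the diet in WT, 10 for the diet in iKO and 6 for the interaction. With an estimated correlation they were 4, 1, 2, 5 and 1, and by fry 6, 8, 13, 13 and 2. Markers of white adipocytes (3 tested members), brown adipocytes (3), lymphocytes (3), mesothelium (1) and lung epithelium (0) were too few to test. Results of 2 single genes are not reported here, although both stay in their lists. Scores of a list are the mean of its members' log2 values after each gene was centred on its mean over all libraries.

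Named genes were, per pairwise contrast, Acacb and Acaca, up to 10 largest increases and 10 largest decreases among called genes with a mean log2 value of at least 1, and up to 4 called members of each list by smallest p. Where a list called by camera had no called member, its member with the smallest p was taken, and for the interaction the 5 highest and 5 lowest were taken by the same rule. Park2, Pink1, Esr1, A1cf, Cpt1b and Pdk4 were included in any case. The text names a part of these, and genes outside the rule are marked where they appear.

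The depth was estimated from the steps of 1 read in FPKM of short single-transcript genes (130 to 450 nt), with the effective length taken as the length less the read length plus 1. The offset was first explored on the values and then fixed from the read length. In each library 110 to 162 such genes were used, and 67.4% to 82.8% of their values were whole to within 0.05 reads. The estimates lie between 12.5 and 32 M assigned reads. Whole reads were not recoverable for most genes, possibly because expected counts are split between transcripts, which was not tested. The values of mitochondrially encoded genes are uncertain, because they share reads with nuclear copies.

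Alternatives were median-of-ratios and upper-quartile scaling of FPKM, removal of mitochondrially encoded genes, their nuclear copies and haemoglobin genes with the rest rescaled to an equal sum, no filter, a minimum of 1 FPKM, sample quality weights, a fit of only the groups compared, and leaving out each library in turn. A pseudocount of 0.1, the first principal component of the residuals as covariate, median-of-ratios scaling for the list tests, and leaving out RT4 with RT7 or RT1 with RT4 were chosen after seeing the data. The residual component comes from the residuals of the same fit. It cannot change a fold change, and its counts of called genes differ through the estimated error alone. For correlations and medians over gene sets, a value was taken as moved when it differed by more than the SD over the fits that left out 1 library, and by at least 0.01, which is a choice of this processing. Permutation tests of list scores were two-sided, exact over 252 splits within a diet and with 100000 resamples for the difference between diets. Fisher's exact test for genes near A1cf was used with called genes counted within 5 Mb on either side.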

Results

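Poly(A) RNA of the left ventricle was sequenced from 20 male mice in 4 groups of 5, formed by genotype and diet. The iKO mice carried floxed alleles of Acacb and MerCreMer, a tamoxifen-inducible Cre recombinase. Their littermates with the floxed alleles and without the Cre are called WT in the labels and here, and both genotypes received tamoxifen. Acacb encodes ACC2, the acetyl-CoA carboxylase at the outer mitochondrial membrane whose product malonyl-CoA inhibits fatty acid entry into mitochondria. From 4 weeks after tamoxifen the mice ate chow or a high-fat diet (HFD, Research Diets D12492) for 16 weeks, per the labels' protocols. The values are FPKM for 25052 genes, of which 12775 were tested. The reads assigned to genes, estimated from the steps between low values, numbered from 12.5 M in iKO chow library RT7 to 32 M in WT HFD library RT18, with a median of 22.4 M. Their group means were 21.3 M ± 1.18 (SD, n = 5) in WT on chow, 19.9 ± 4.93 in iKO on chow, 27.9 ± 3.44 in WT on HFD and 23.1 ± 3.82 in iKO on HFD. Libraries RT1 to RT10 are all chow and RT11 to RT20 all HFD, and the labels give no batch, so that any difference between these runs of numbers and the diet cannot be told apart.

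The first comparison asked whether each library carried the genotype of its label. Acacb (ENSMUSG00000042010.16, chromosome 5, 114146535 to 114250761 on GRCm38) stood at 38.6 FPKM ± 1.57 (SD, n = 5) in WT on chow and 8.95 ± 0.464 in iKO on chow. On HFD it stood at 37.8 ± 2.93 in WT and 10.6 ± 1.13 in iKO. The 10 WT libraries lay between 34.9 and 41.92 FPKM and the 10 iKO libraries between 8.37 and 11.92. Acacb fell by 1.99 on the log2 scale on chow (SE 0.06, adjusted p = 1.03e-15) and by 1.74 on HFD (SE 0.06, adjusted p = 1.90e-14). Esr1 (ENSMUSG00000019768.16, chromosome 10, 4611593 to 5005614), whose ligand-binding sequence is part of MerCreMer, stood at 1.41 FPKM ± 0.278 in WT on chow and 1086 ± 340 in iKO on chow. On HFD it stood at 0.838 ± 0.681 in WT and 813 ± 377 in iKO, and these values include reads from the transgene. Xist reached at most 0.01 FPKM and the Y-linked Ddx3y lay between 17.52 and 24.57 FPKM, as in male mice. Acaca, the gene of the cytosolic carboxylase ACC1, did not pass the test between genotypes on chow (log2 fold change 0.16, SE 0.08, adjusted p = 0.389) or on HFD (0.19, SE 0.08, adjusted p = 0.294).

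**Figure D1:**
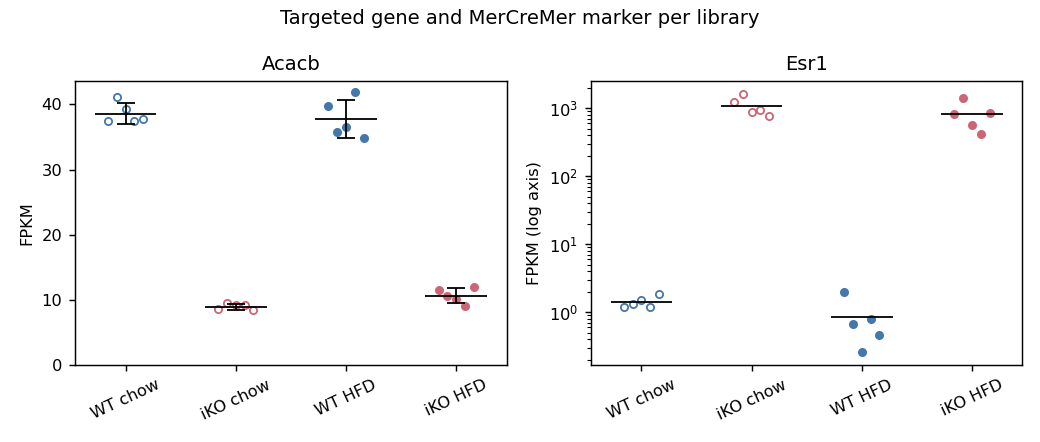
Acacb (left, FPKM, lines for the mean and bars for the SD) and Esr1 (right, FPKM on a log axis, lines for the mean) in each of the 20 libraries, by group of 5. Acacb lies between 34.9 and 41.92 FPKM in WT and between 8.37 and 11.92 in iKO.

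The comparison of iKO with WT on chow asked what loss of ACC2 did to the ventricular transcriptome without a change of diet. Genes of fatty acid use were lower in iKO. Of the 32 tested PPAR-alpha targets, genes that the fatty acid sensor PPAR-alpha activates, 21 fell and none rose (27 fell when adjusted over the list alone), with a median log2 fold change of -0.31. Acot1, an acyl-CoA thioesterase, fell from 7.25 FPKM ± 0.987 to 3.04 ± 0.812 (SD, n = 5), and Fabp3, the fatty acid-binding protein of heart muscle, from 3435 ± 55.8 to 2613 ± 75.8. Of 23 genes of mitochondrial fatty acid oxidation 16 fell (19 adjusted over the list alone, median -0.25), among them Acaa2, a thiolase, from 538.2 FPKM ± 21.4 to 370.7 ± 21.6. Decr1, the dienoyl-CoA reductase, fell by 0.53 (SE 0.04, adjusted p = 1.38e-07), Slc25a20, the carnitine-acylcarnitine carrier, by 0.43 (adjusted p = 4.39e-06), and Cpt1b, the malonyl-CoA-sensitive carnitine transferase of muscle, by 0.28 (SE 0.05, adjusted p = 0.00124). Of 28 genes of fatty acid uptake, activation and lipid storage 6 fell (10 adjusted over the list alone, median -0.10), including the lipoprotein lipase Lpl by 0.28 and the lipoprotein receptor Vldlr by 0.50. Camera gave adjusted p = 1.86e-69 for the PPAR-alpha targets (0.000427 with an estimated correlation), 1.68e-57 for oxidation (0.00104 with an estimated correlation) and 3.40e-14 for uptake (0.00242 with an estimated correlation). The PPAR-alpha targets share members with both other lists, so that their tests are not independent.

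Beyond these lists the largest decreases on chow were those of Acacb, Scd4, Scn4b and Cox6b2. Scd4, a stearoyl-CoA desaturase, fell by 1.26 (SE 0.12, adjusted p = 7.07e-07) and Scn4b, a sodium channel beta subunit, from 17.9 FPKM ± 2.27 to 7.68 ± 1.42. Fbp2, the muscle fructose bisphosphatase, fell from 17.7 FPKM ± 0.667 to 9.12 ± 0.881, and Fah, the last enzyme of tyrosine breakdown, by 0.83 (adjusted p = 1.12e-06). Pdk4, an inhibitory kinase of pyruvate dehydrogenase, had a log2 fold change of -1.07 that did not pass the test (SE 0.36, adjusted p = 0.206). Among the increases, A1cf, an RNA-binding cofactor of apolipoprotein B mRNA editing, rose by 0.90 (SE 0.11, adjusted p = 2.61e-05) to 0.89 FPKM ± 0.353, from at most 0.01 in the WT libraries. Tac1, the substance P precursor, rose by 0.65, Ndrg4 by 0.49, and Prkg1, a cGMP-dependent kinase, by 0.48 (adjusted p = 0.0156). The call of Prkg1 was lost without RT4 or RT10 (highest adjusted p = 0.0615). Prkg1 is a neighbour of A1cf on the same chromosome. For both genes, on either diet, an effect of the Cre transgene or its insertion cannot be told apart from ACC2 loss. Park2 (log2 fold change 0.17, adjusted p = 0.374) and Pink1 (-0.031, adjusted p = 0.827), which mark damaged mitochondria for removal, did not pass the test.

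Of the other lists called downward on chow, ketone body metabolism alone held with an estimated correlation. The median log2 fold change of all genes was 0.05 for genotype on chow, and camera compares a list with the other genes. Of 6 genes of ketone body metabolism 2 fell (2 adjusted over the list alone, median -0.12, camera adjusted p = 0.000338, adjusted p = 0.0157 with an estimated correlation). Without RT4 and RT7 together the count was 0, with adjusted p = 0.134 with an estimated correlation, and under median-of-ratios scaling this p was 0.0622. No member fell among 21 genes of branched-chain amino acid catabolism (median -0.076, adjusted p = 3.55e-09 and 0.057 with an estimated correlation), 20 of the tricarboxylic acid cycle (median -0.040, 1.53e-05 and 0.442) or 75 nuclear-encoded respiratory chain subunits (median -0.023, 2.54e-07 and 0.592). The 13 mitochondrially encoded genes had a median of -0.062 (adjusted p = 0.000135 and 0.478 with an estimated correlation) and camera gave 0.129 without RT4. In malonyl-CoA metabolism and de novo lipogenesis 3 of 13 genes fell (3 adjusted over the list alone), which were Acacb itself, Me1 and Mlycd, the malonyl-CoA decarboxylase. The list's median of 0.078 differed in sign from its mean of -0.11 and from camera (adjusted p = 0.0129 and 0.442 with an estimated correlation). Its mean and its call include Acacb, the deleted gene, and camera was not run without it.

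Camera called several lists upward in iKO on chow, none of them with an estimated correlation, while endothelial markers (median 0.015) and smooth muscle and pericyte markers (-0.027) were not called. The 7 lists called upward became 2 without RT10 and 4 without RT2, RT4 or RT7. All 11 fibroblast markers had log2 fold changes above 0 (median 0.41), with no member called (0 adjusted over the list alone), and their mean score was -0.16 ± 0.089 (SD, n = 5) in WT and 0.24 ± 0.43 in iKO, highest in RT4 at 0.84, with RT6 and RT9 at -0.14 and -0.11, within the range of WT. Camera gave adjusted p = 0.000338 for these markers (0.592 with an estimated correlation). For extracellular matrix and fibrosis the median was 0.23 (adjusted p = 0.00593 and 0.740 with an estimated correlation), and without RT4 alone camera gave 0.355. For macrophage markers it was 0.23 (0.0410 and 0.740), which became 0.129 without RT4. For interferon-stimulated genes it was 0.22 (0.0470 and 0.740, with 2 members higher adjusted over the list alone), which became 0.149 without RT4. Immediate-early genes had a median of 0.25 (adjusted p = 0.0104 and 0.592 with an estimated correlation, 1 member higher adjusted over the list alone) and erythroid markers 0.31 (0.0129 and 0.592). Of 13 genes in the neighbourhood of A1cf on chromosome 19, 3 rose (3 adjusted over the list alone, median 0.11, adjusted p = 0.0470 and 0.505 with an estimated correlation), and 1 without RT1 and RT4 together. Transcripts of atrial muscle were high in WT chow library RT1 (Myl7 145.15 FPKM, Sln 56.18) and iKO chow library RT4 (Myl7 30.81, Sln 6.2), against at most 2.88 FPKM for Myl7 in the others.

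On chow limma called 136 genes, 44 higher and 92 lower in iKO, and 7 of them changed by more than 1 on the log2 scale. Under median-of-ratios scaling the split was 19 higher and 124 lower, and under upper-quartile scaling 21 and 117. With the first residual component as covariate, added after the data were seen, 297 were called higher and 120 lower. This covariate left the fold changes as they were (median of all genes 0.05) and changed their error alone. The higher genes numbered 18 without RT4, 21 without RT3 or RT5, 22 without RT10, 23 without RT8 and 25 without RT7. Without RT1 and RT4 together, a choice made after their atrial transcripts were seen, 87 genes were called, 16 higher and 71 lower, and 16 PPAR-alpha targets fell. Without RT4 and RT7 together, chosen after the depth estimate was seen, 74 genes were called.

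**Figure D2:**
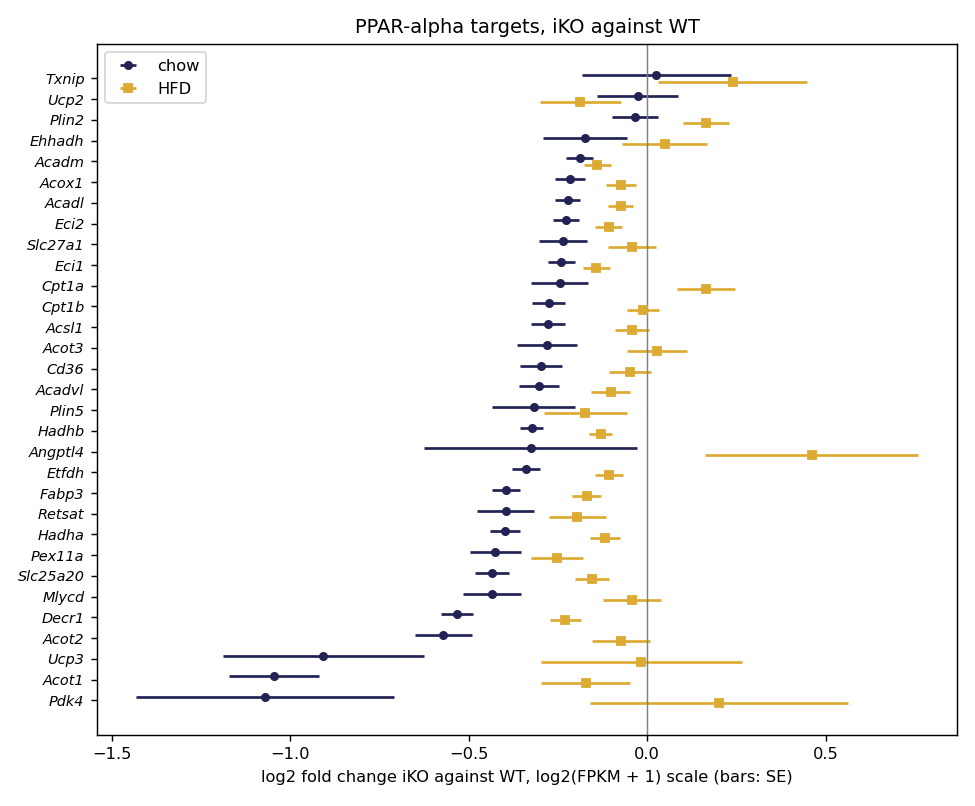
Log2 fold change of iKO against WT for the tested PPAR-alpha targets on chow and on HFD, with bars for the SE and 1 of the 32 not shown. The median of all 32 is -0.31 on chow, where 21 targets fell, and -0.073 on HFD, where 1 fell.

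The comparison of iKO with WT on HFD asked what loss of ACC2 did when dietary fat was high. Of 24 tested genes of the integrated and mitochondrial stress response 4 rose in iKO (8 adjusted over the list alone, median 0.18, camera adjusted p = 2.18e-05, adjusted p = 0.158 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 1.83 FPKM ± 0.368 to 5.68 ± 1.82 (SD, n = 5; log2 fold change 1.19, SE 0.18, adjusted p = 0.00632). Atf5, a transcription factor of the mitochondrial unfolded protein response, rose from 16.7 FPKM ± 1.5 to 27.4 ± 4.19 (0.67, SE 0.09, adjusted p = 0.000984). Asns, the asparagine synthetase, stood at 0.966 FPKM ± 0.238 and 1.95 ± 0.353 (adjusted p = 0.0331), and Trib3, a pseudokinase induced by ATF4, at 1.59 ± 0.189 and 2.51 ± 0.374 (adjusted p = 0.0343). The calls of Asns and Trib3 were both lost without any single one of RT12, RT13, RT14, RT15, RT16 and RT18 (highest adjusted p = 0.119), that of Trib3 also without RT17 or RT19 and that of Asns without RT20. With an estimated correlation the list's p was 0.0350 without RT4. RT4 is a chow library outside this comparison, so leaving it out changes the residuals and no fold change on HFD. This test was not repeated without single HFD libraries. For the list fry gave adjusted p = 0.00197 in the direction of a rise. Irs2, an insulin receptor substrate, rose by 0.46 (SE 0.08, adjusted p = 0.00998) and Prkg1 by 0.71 (SE 0.10, adjusted p = 0.00175).

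**Figure D3:**
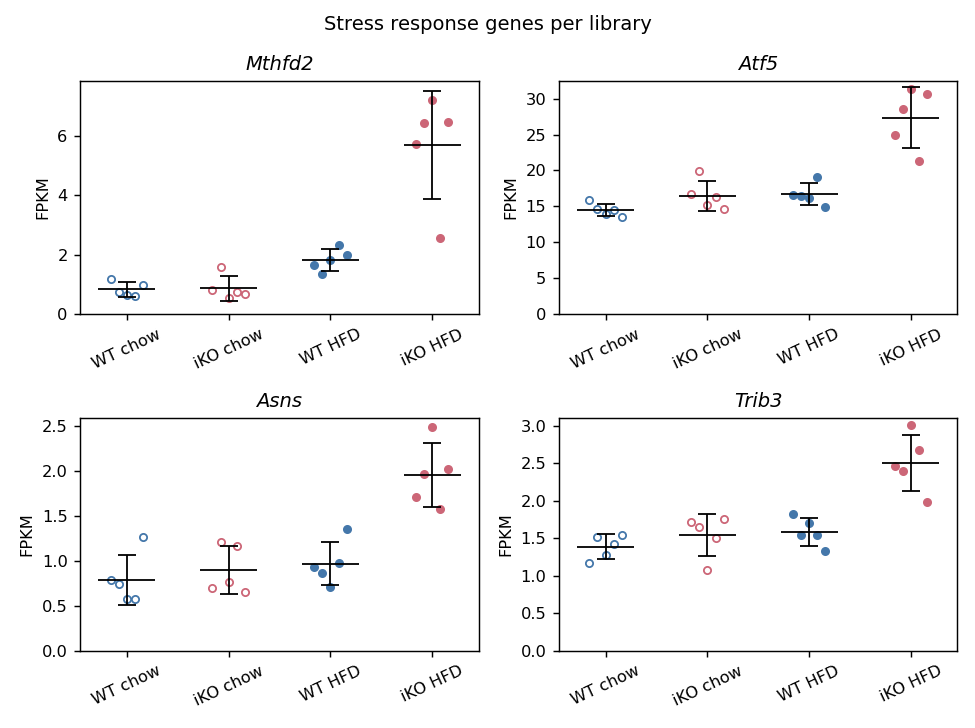
Mthfd2, Atf5, Asns and Trib3 in FPKM in each of the 20 libraries, by group of 5, with lines and bars for the mean and SD. In iKO on HFD Mthfd2 averages 5.68 FPKM and Atf5 27.4, against 1.83 and 16.7 in WT on HFD.

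Camera called the lists of fatty acid use downward in iKO on HFD too, none of them with an estimated correlation. Of 23 genes of mitochondrial fatty acid oxidation 2 fell, Acaa2 by 0.23 and Decr1 by 0.23 (adjusted p = 0.0343 and 0.0331), and 14 fell when adjusted over the list alone (median -0.12, camera adjusted p = 2.02e-22, adjusted p = 0.0723 with an estimated correlation). Of the 32 PPAR-alpha targets 1 fell, and 10 adjusted over the list alone (median -0.073, 4.56e-15, adjusted p = 0.143 with an estimated correlation). Fatty acid uptake, activation and lipid storage had no called member and 2 lower adjusted over the list alone (median -0.014, 0.00140, adjusted p = 0.218 with an estimated correlation). Branched-chain amino acid catabolism also had none called, with 3 lower adjusted over the list alone (median -0.094, 8.83e-16). It was the list called on HFD with an estimated correlation (adjusted p = 0.0342, and 0.177 under median-of-ratios scaling). Cpt1b (log2 fold change -0.011, adjusted p = 0.922), Fabp3 (-0.17, adjusted p = 0.105), Pdk4 (0.20, adjusted p = 0.801), Park2 (0.20, adjusted p = 0.278) and Pink1 (-0.049, adjusted p = 0.653) did not pass the test. Fbp2 fell by 0.34 (adjusted p = 0.0331), and Kcnip2, a subunit of the transient outward potassium channel, rose by 0.32 (adjusted p = 0.0343, and 0.126 under median-of-ratios scaling).

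The median log2 fold change of all genes was 0.063 for genotype on HFD, and camera compares a list with the other genes. Other lists were called on HFD by camera without an estimated correlation. The 8 called upward became 4 without RT13 or RT16 and 5 without RT20. Lower were the 75 respiratory chain subunits (median -0.060, adjusted p = 3.51e-26 and 0.166 with an estimated correlation), the tricarboxylic acid cycle (-0.040, 8.74e-06 and 0.349), mitochondrially encoded genes (-0.027, 0.00140 and 0.415), erythroid markers (-0.076, 0.0141 and 0.456) and proliferation (-0.033, 0.0163 and 0.415, and 0.112 by camera under median-of-ratios scaling). Malonyl-CoA metabolism and de novo lipogenesis, where Acacb alone fell (1 adjusted over the list alone), had a median of 0.092, a mean of -0.063 and a call downward (0.0201 and 0.383). The mean and the call of this list include the deletion of Acacb itself. Ketone body metabolism had a median of 0.004, a mean of -0.004 and a call downward (0.0201 and 0.164), and its median turned to -0.069 under median-of-ratios scaling. Cardiomyocyte markers had a median of -0.025, a mean of 0.011 and a call downward (0.0258 and 0.415). Higher were mitophagy and autophagy (median 0.083, 2 members adjusted over the list alone, 0.0240 and 0.456, and 0.677 by camera under median-of-ratios scaling), cardiac stress and hypertrophy (median 0.20, 1 member, Kcnip2, called and 5 adjusted over the list alone, 0.0344 and 0.455) and immediate-early genes (0.29, 0.00140 and 0.415). The cardiac stress list joins natriuretic peptide genes with ion channel genes such as Kcnip2, so that its direction alone does not measure stress. Heat shock genes (0.16, 0.0301 and 0.638), interferon-stimulated genes (0.21, 1 member adjusted over the list alone, 0.0201 and 0.634) and the neighbourhood of A1cf on chromosome 19 (0.13, 1 member called and 2 adjusted over the list alone, 0.0344 and 0.415) were higher as well. The 11 fibroblast markers were again all above 0 (median 0.36, 0.00587 and 0.534), with a mean score of -0.22 ± 0.094 (SD, n = 5) in WT and 0.15 ± 0.39 in iKO, where RT13, RT15 and RT17 stood at 0.46, 0.39 and 0.45 but RT11 and RT20 at -0.30 and -0.27, within the range of WT.

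On HFD limma called 22 genes, 13 higher and 9 lower in iKO, and 8 and 17 under median-of-ratios scaling. With the first residual component as covariate, which cannot change the fold changes, it called 339 higher and 46 lower, and with quality weights 67 and 28. The count was 39 without RT11, 6 without RT12, 10 without RT13, 8 without RT15, 7 without RT16, 10 without RT17, 8 without RT18 and 11 without RT19. Acacb, Esr1, Atf5, Prkg1, Irs2 and Mthfd2 were called in each of the 10 fits that left out 1 library. Each of Acaa2, Decr1, Fbp2, Kcnip2, Trib3 and Asns lost its call in 7 or 8 of these fits, with adjusted p up to 0.149, each without RT12, RT13, RT15 or RT16 and some without RT14, RT17, RT18, RT19 or RT20.

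The comparison of HFD with chow in WT asked what the diet did in hearts with ACC2. Of the 32 PPAR-alpha targets 21 rose and none fell (25 adjusted over the list alone, median 0.23). Pdk4 rose from 99.9 FPKM ± 40.4 to 305.9 ± 110.8 (SD, n = 5; adjusted p = 0.0126) and Acot1 from 7.25 ± 0.987 to 16.9 ± 1.58 (adjusted p = 1.83e-05). Angptl4, an inhibitor of lipoprotein lipase, rose by 1.42 (SE 0.30, adjusted p = 0.00908) and Decr1 by 0.44 (SE 0.04, adjusted p = 3.84e-06). Tfrc, the transferrin receptor, rose from 5.92 FPKM ± 1.19 to 23.7 ± 7.47. Of 23 genes of mitochondrial fatty acid oxidation 11 rose and none fell (14 and 2 adjusted over the list alone, median 0.12), while Cpt1b had a log2 fold change of 0.074 (adjusted p = 0.305). Of 28 genes of fatty acid uptake, activation and lipid storage 6 rose and 1, Lpl, fell (9 and 4 adjusted over the list alone, median 0.057). Camera gave adjusted p = 3.04e-57 for the PPAR-alpha targets (0.00129 with an estimated correlation), 2.07e-26 for oxidation (0.0392 with an estimated correlation, 0.0807 under median-of-ratios scaling and 0.0503 without RT4) and 4.44e-07 for uptake (0.0562 with an estimated correlation). RT4 is an iKO library and enters this comparison through the residuals alone. Ucp3, an uncoupling protein, rose by 1.04 (adjusted p = 0.0315), and the call was lost without any single one of RT1, RT5, RT8, RT10, RT12, RT18 and RT19 (highest adjusted p = 0.0743).

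Of the lists that camera called downward on HFD in WT, none held with an estimated correlation, and fewer of their members fell under median-of-ratios scaling. Nppb, the B-type natriuretic peptide, fell from 191.4 FPKM ± 56.7 to 57.96 ± 15.9 (SD, n = 5; adjusted p = 0.00389). Nppa fell by 1.69 (SE 0.47, adjusted p = 0.0369), was at 351.85 FPKM in RT1 with its atrial transcripts, and lost its call without any single one of RT1, RT5, RT8, RT12, RT16 and RT18 (highest adjusted p = 0.0873). Abat, the GABA transaminase, fell from 7.18 FPKM ± 1.12 to 1.60 ± 0.311 (adjusted p = 1.34e-08), and Oxct1, which activates ketone bodies for oxidation, from 413.7 ± 19.4 to 313.0 ± 17.3. Of 21 genes of branched-chain amino acid catabolism 12 fell (18 adjusted over the list alone, median -0.20, camera adjusted p = 9.85e-09, adjusted p = 0.0771 with an estimated correlation), but 1 fell under median-of-ratios scaling. Of 17 genes of sterol synthesis 5 fell (9 adjusted over the list alone, median -0.17, 0.00927, adjusted p = 0.164 with an estimated correlation), among them Idi1 by 0.41 and the regulator Srebf2 by 0.36, and 2 fell under median-of-ratios scaling. In cardiac stress and hypertrophy 8 of 26 fell (8 adjusted over the list alone, median -0.20, 0.0115, adjusted p = 0.374 with an estimated correlation), with 2 under median-of-ratios scaling and 4 without RT1 and RT4. Of 14 cardiomyocyte markers 9 fell (11 adjusted over the list alone, median -0.21, 2.65e-05, adjusted p = 0.0989 with an estimated correlation), and 3 under median-of-ratios scaling. Myl3, a ventricular myosin light chain, fell by 0.36 (adjusted p = 0.000153), and Myl2 by 0.30 (adjusted p = 0.00248, and 0.173 under median-of-ratios scaling). Acaca fell by 0.29 (adjusted p = 0.0349, and 0.150 under median-of-ratios scaling) and lost its call without any single one of RT1, RT3, RT8, RT12, RT14, RT16 and RT19 (highest adjusted p = 0.103).

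Of 13 mitochondrially encoded genes 3 rose in WT on HFD (5 adjusted over the list alone, median 0.13, camera adjusted p = 1.14e-11, adjusted p = 0.0771 with an estimated correlation), among them mt-Nd2 by 0.19. Mitochondrially encoded genes and their nuclear copies share reads and held 56.9% ± 0.568 of the FPKM (SD, n = 5) in WT on chow, 55.6% ± 2.67 in iKO on chow, 60.5% ± 1.21 in WT on HFD and 59.3% ± 0.643 in iKO on HFD. The median log2 fold change of all genes was -0.084 in WT and -0.072 in iKO with HFD. Nuclear-encoded respiratory chain subunits had a median of -0.080, with 4 of 75 lower (0 adjusted over the list alone, 0.0378, adjusted p = 0.859 with an estimated correlation), and of 0.023 with none lower under median-of-ratios scaling. All 4 calls were lost without any single one of RT3, RT10, RT12, RT14 and RT18 (highest adjusted p = 0.126). The integrated and mitochondrial stress response had 1 member higher and 2 lower (1 and 4 adjusted over the list alone), with a median of -0.021, a mean of 0.044 and a call upward (0.00984 and 0.374 with an estimated correlation), and its median turned to 0.067 under median-of-ratios scaling. Interferon-stimulated genes had a median of -0.022, a mean of 0.008 and a call upward (0.0107 and 0.617), and their median turned to 0.048 under median-of-ratios scaling, where camera gave 0.155. The neighbourhood of A1cf on chromosome 19 had a median of -0.003, a mean of 0.027 and a call upward (0.0353 and 0.374), and its median turned to 0.034 under median-of-ratios scaling. Erythroid markers (median 0.18, 0.00160 and 0.405) and proliferation (0.003, 0.00984 and 0.374, and 0.133 by camera under median-of-ratios scaling) were called upward with no member called.

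In WT limma called 1027 genes, 98 higher and 929 lower on HFD, and 13 of them changed by more than 1 on the log2 scale. The split depended on the scaling, with 179 higher and 159 lower under median-of-ratios, 148 and 205 under upper-quartile scaling, and 160 and 150 with mitochondrial and haemoglobin genes removed. Of the 1027 genes 257 were called under median-of-ratios scaling too, and the count was 623 without RT3 and 660 without RT1. The lower genes numbered 543 without RT3, 581 without RT1 and 606 without RT14.

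The comparison of HFD with chow in iKO asked what the diet did in hearts that had lost ACC2. Of the 32 PPAR-alpha targets 30 rose and none fell (32 adjusted over the list alone, median 0.48). Pdk4 rose from 46.98 FPKM ± 21 to 342.1 ± 107.1 (SD, n = 5; adjusted p = 9.15e-05) and Acot1 from 3.04 ± 0.812 to 14.95 ± 2.46 (adjusted p = 1.21e-09). Of 23 genes of mitochondrial fatty acid oxidation 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.34), among them Decr1 by 0.74 and Cpt1b by 0.34 (adjusted p = 4.17e-05). Of 28 genes of fatty acid uptake, activation and lipid storage 12 rose and 1 fell (13 and 2 adjusted over the list alone, median 0.20), including the fatty acid transporter Cd36 by 0.46 and the lipid droplet protein Plin2 by 0.47. Camera gave adjusted p = 1.72e-89 for the PPAR-alpha targets (9.13e-05 with an estimated correlation), 4.22e-44 for oxidation (0.00272 with an estimated correlation) and 7.23e-14 for uptake (0.00272 with an estimated correlation). In the integrated and mitochondrial stress response 6 of 24 rose and 1 fell (8 and 3 adjusted over the list alone, median 0.077, 6.90e-08, adjusted p = 0.0455 with an estimated correlation). Mthfd2 rose from 0.876 FPKM ± 0.419 to 5.68 ± 1.82 (log2 fold change 1.80, SE 0.18, adjusted p = 2.00e-06) and Atf5 from 16.5 ± 2.08 to 27.4 ± 4.19. Scn4b rose by 1.35 (SE 0.11, adjusted p = 3.47e-08), Ucp3 by 1.93 (SE 0.28, adjusted p = 0.000334) and Tfrc by 1.29 (SE 0.20, adjusted p = 0.000420).

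Of the lists that camera called downward on HFD in iKO, branched-chain amino acid catabolism alone held with an estimated correlation. Abat fell by 1.58 (SE 0.11, adjusted p = 4.20e-09), Oxct1 by 0.43 (adjusted p = 3.45e-06) and Pcx, the pyruvate carboxylase, by 0.52. Of 21 genes of branched-chain amino acid catabolism 14 fell (16 adjusted over the list alone, median -0.21, camera adjusted p = 6.69e-10, adjusted p = 0.0455 with an estimated correlation), against 5, and adjusted p = 0.386 with an estimated correlation, under median-of-ratios scaling. Of 17 genes of sterol synthesis 6 fell (7 lower and 1 higher adjusted over the list alone, median -0.14, 0.0303, adjusted p = 0.276 with an estimated correlation), and 2 without RT4 and RT7. Of 14 cardiomyocyte markers 9 fell (10 adjusted over the list alone, median -0.27, 8.30e-06, adjusted p = 0.0685 with an estimated correlation), and 4 under median-of-ratios scaling. Of 75 nuclear-encoded respiratory chain subunits 20 fell (44 adjusted over the list alone, median -0.12, 3.51e-08, adjusted p = 0.628 with an estimated correlation), but none fell under median-of-ratios scaling, where camera gave 0.0638. Of 13 mitochondrially encoded genes 5 rose (6 adjusted over the list alone, median 0.17, 4.30e-11, adjusted p = 0.0685 with an estimated correlation), and 3 without RT4. Interferon-stimulated genes had a median of 0.048 with no member called (0.0187 and 0.785 with an estimated correlation), and camera gave 0.118 under median-of-ratios scaling. A1cf fell by 0.43 within iKO (SE 0.11, adjusted p = 0.0134). What remained of Acacb rose by 0.22 (SE 0.06, adjusted p = 0.0278), a call lost without any single one of RT2, RT9, RT11, RT13 and RT20 (highest adjusted p = 0.0809). Acaca fell by 0.26 (adjusted p = 0.0464), and its call was lost without any single one of RT2, RT4, RT7, RT9, RT11, RT13, RT15, RT17 and RT20 (highest adjusted p = 0.111).

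In iKO limma called 1279 genes, 211 higher and 1068 lower on HFD. Under median-of-ratios scaling 325 were higher and 246 lower, under upper-quartile scaling 288 and 306, and with mitochondrial and haemoglobin genes removed 345 and 214. Without RT1 and RT4 together 839 genes were called, and without RT4 and RT7 together 509. The lower genes numbered 711 without RT4 and 705 without RT11.

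The interaction asked whether the diet effect differed between iKO and WT. Limma called 4 genes, each with an interaction above 0, and 0 genes with one below 0, against 480 genes at an unadjusted p under 0.05 in either direction. Vwa8, a mitochondrial ATPase (ENSMUSG00000058997.7, chromosome 14, 78849052 to 79202310), stood at 42.66 FPKM ± 1.62 (SD, n = 5) in WT on chow and 29.0 ± 1.16 in iKO on chow. On HFD Vwa8 stood at 51.4 ± 4.71 in WT and 47.4 ± 2.26 in iKO (interaction 0.43, SE 0.08, adjusted p = 0.0466). The interaction was 0.55 for Fbp2 (SE 0.09, adjusted p = 0.0345), 0.86 for Scn4b (SE 0.15, adjusted p = 0.0466) and 0.99 for Scd4 (SE 0.17, adjusted p = 0.0345). Scd4 fell with HFD in WT by 0.52 and rose in iKO by 0.46, while the other 3 genes rose in both. It did not pass the test for Mthfd2 (1.18, adjusted p = 0.232), Acot1 (0.87, adjusted p = 0.174), Decr1 (0.30, adjusted p = 0.174), Cpt1b (0.27, adjusted p = 0.278), Pdk4 (1.27, adjusted p = 0.999) or Acacb (0.25, adjusted p = 0.989). As groups, the PPAR-alpha targets had a median interaction of 0.23 (0 members called, 19 higher adjusted over the list alone, camera adjusted p = 1.14e-33, adjusted p = 0.0187 with an estimated correlation). The latter p was 0.0605 without RT4, 0.0554 without RT1 and RT4, 0.161 without RT4 and RT7 and 0.133 under median-of-ratios scaling. Mitochondrial fatty acid oxidation had a median of 0.19 (13 higher adjusted over the list alone, 7.70e-21, adjusted p = 0.0935 with an estimated correlation) and fatty acid uptake, activation and lipid storage of 0.081 (4 higher, 9.16e-06, adjusted p = 0.109 with an estimated correlation). The integrated and mitochondrial stress response had a median of 0.082 (3 higher, 0.000107, adjusted p = 0.233 with an estimated correlation), erythroid markers of -0.40 (3.07e-06 and 0.288) and respiratory chain subunits of -0.042 (2.18e-05 and 0.785). The number of genes called was 0 under median-of-ratios and upper-quartile scaling and without any single one of RT1, RT3, RT4, RT5, RT8, RT13, RT15, RT16, RT18, RT19 and RT20. It was 1 without RT2, RT6, RT9 or RT14 and 2 without RT10 or RT12.

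Genotype effects on chow and on HFD, which rest on separate libraries, were compared across genes, which are not independent replicates. Over 12775 genes Pearson's r was 0.602 and Spearman's rho 0.381, and r was 0.455 without Esr1 and Acacb. Both diets shared 14 called genes, 5 higher where 0.04 were expected by chance and 9 lower where 0.06 were expected. The 5 higher were Esr1, Prkg1, Ndrg4, Ten1 and Rbpms2, and the 9 lower were Acacb, Fbp2, Acaa2, Decr1, Dbi, Ephx2, Armc2, Gstm6 and Gm34302. The shared count was 3 without RT12, 4 without RT15, RT16 or RT18, 5 without RT19, 6 without RT17, 7 without RT8 or RT13 and 8 without RT10. It was 3 without a filter on low values and 25 with quality weights. With the first residual component as covariate, where r stayed at 0.602, it was 123, with 99 higher and 24 lower. On HFD Ten1 lost its call in 9 of the 10 fits that left out 1 library and Ndrg4 in 6. Both lost it under median-of-ratios scaling (adjusted p = 0.0819 and 0.104). Of the 136 genes called on chow 126 had the same sign on HFD. Diet effects in WT and in iKO had an r of 0.611 and a rho of 0.509, with 74 genes higher in both (1.62 expected) and 461 lower in both (77.67 expected). Under median-of-ratios scaling 117 were higher in both (4.55 expected) and 74 lower in both (3.06 expected).

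The last comparison asked whether loss of ACC2 on HFD turned back what HFD had changed in WT. The 98 genes that rose with HFD in WT had a median genotype effect on HFD of -0.15 relative to all genes, and the 929 that fell had one of 0.005. Both contrasts use the same WT HFD libraries, and simulated groups without any change gave -0.11 and 0.073 for the same reason. With these libraries split between the contrasts in 20 ways the medians were -0.11 (-0.14 to -0.001) and -0.041 (-0.087 to -0.015). In each split the 98 and 929 genes were picked anew by smallest p. Genes that rose and genes that fell both lay below all genes in every split. A turning back would place the genes that fell above all genes, which no split did. The value of those that fell changed sign with the split and without RT12 or RT15 (-0.003 each).

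A1cf (ENSMUSG00000052595.6, chromosome 19, 31868764 to 31948995 on GRCm38) was listed between 0 and 0.01 FPKM in all WT libraries and between 0.11 and 1.31 in all iKO libraries. Its neighbours Prkg1 (ENSMUSG00000052920.14, 30564489 to 31765033) and Rnls (ENSMUSG00000071573.13, 33137747 to 33392295) rose on chow by 0.48 and 0.51, and Prkg1 rose on HFD by 0.71. On HFD A1cf (0.46, adjusted p = 0.104), Rnls (0.26, adjusted p = 0.245) and Lipo2 (0.99, adjusted p = 0.110) did not pass the test. Lipo2 (ENSMUSG00000087303.2, 33719670 to 33751359), a lipase gene of the same chromosome that was chosen after its values were seen, rose on chow by 1.58 (SE 0.23, adjusted p = 0.000677). The call of Prkg1 on chow was lost without RT4 or RT10 (highest adjusted p = 0.0615). Within 5 Mb of A1cf 3 genes fell on chow, Vldlr by 0.50, Kcnv2 by 0.66 and Pank1 by 0.40 (adjusted p = 0.000741, 0.000882 and 0.00263). Lipo2 overlaps Lipo3, so that reads may be shared between them.

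**Figure D4:**
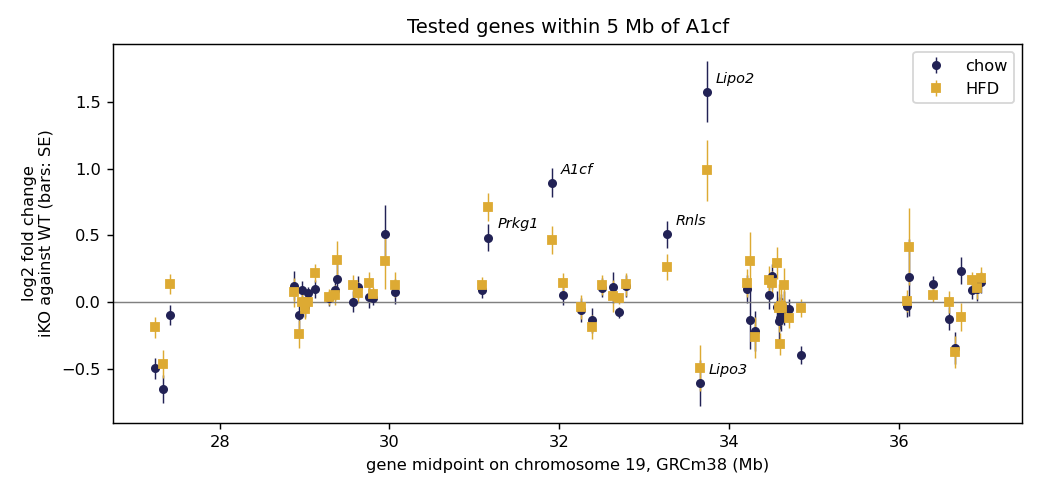
Log2 fold change of iKO against WT (bars for the SE) for tested genes within 5 Mb of A1cf, by position on chromosome 19, on chow and on HFD. A1cf lies at 0.90 on chow and 0.46 on HFD, Prkg1 at 0.48 and 0.71, and Lipo2 at 1.58 and 0.99.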

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

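The tests of scaling and connective tissue for the PPAR-alpha targets, of the density of called genes around A1cf, of the transgene acting on Lipo2 and Rnls, and of the diet difference of the stress response score were chosen after the result was seen, and so was the condition that a value pass its bound by more than its spread.

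In 12 of 347 groups of 5 libraries over 87 genes, 1 library lay far from the others, measured as its gap to the nearest library divided by the group's range, where about 17 are expected by chance. On chow in iKO the ratio was 0.755 for Acaca (lowest in RT6, 1.98 FPKM, next 2.58), 0.744 for Hadhb (lowest in RT4, 997.9 against 1028.82) and 0.712 for Irs2 (lowest in RT2, 1.73 against 2.05). On chow in WT it was 0.826 for Ucp3 (highest in RT3, 25.97 FPKM against 13.84), 0.902 for Hsd17b10 (lowest in RT1, 99.17 against 107.2) and 1 for A1cf (0.01 in RT1, listed at 0 in the others). On HFD in WT it was 0.827 for Ndrg4 (highest in RT14, 63.82 FPKM against 53.72). On HFD in iKO it was 0.773 for Fbp2 (highest in RT20, 22.54 FPKM against 20.86), 0.759 for Vldlr (lowest in RT13, 42.9 against 51.05) and 0.769 for Prkg1 (highest in RT13, 6.7 against 4.76). In the same group it was 0.76 for Mthfd2 (lowest in RT17, 2.57 FPKM against 5.72) and 0.916 for Ten1 (highest in RT15, 6.93 against 5.6).

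The diet effect differed between the genotypes by the interaction for Vwa8 (0.429), Fbp2 (0.549), Scn4b (0.856) and Scd4 (0.987), each of which lost its call in 13 to 17 of 20 fits without 1 library and under median-of-ratios scaling (adjusted p from 0.0914 to 0.124). By camera it differed for mitochondrial fatty acid oxidation (median 0.193), fatty acid uptake, activation and lipid storage (0.081), PPAR-alpha targets (0.23), respiratory chain subunits (-0.042), the integrated and mitochondrial stress response (0.082) and erythroid markers (-0.401). With an estimated correlation PPAR-alpha targets alone were called (adjusted p = 0.0187, but 0.0605 without RT4 and 0.133 under median-of-ratios scaling), and the others, in the order given, had 0.0935, 0.109, 0.785, 0.233 and 0.288.

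For each pairwise comparison, 1 of 100 splits of its 10 libraries, the real split included, gave as many called genes as the real groups. A count as high as the real one was thus rare among the splits. This is the smallest share that 100 splits can give, and it does not bear on single called genes. The real and highest other counts were 136 and 1 for genotype on chow, 22 and 5 for genotype on HFD, 1027 and 0 for the diet in WT and 1279 and 440 for the diet in iKO. For the interaction 4 of 100 relabellings of the genotype within each diet, the real labels included, gave at least the real count of 4, with 150 as the highest other. A count of 150 is several times the real one. The relabelling left the genotype effect in the values, so that labels swapped in 1 diet can turn it into an interaction. These counts therefore do not decide whether chance gave the 4 calls, and the source of the 150 was not tested. The split with 440 exchanged 2 of the 5 libraries of each diet, and splits that exchanged 1 gave at most 14.

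PPAR-alpha targets were lower in iKO on chow, with a median of -0.31. Scaling of the values is argued against by a median of -0.36 after median-of-ratios scaling, and a larger share of connective tissue by a median of 0.011 (SD 0.045) for the cardiomyocyte markers, which would fall along with the targets. For feeding or hormone state at collection, 18 glucocorticoid and FOXO targets had a median of 0.04 (SD 0.106, quartiles 0 and 0.144). This argues against a hormone state that lowers these targets, although it meets the bound, quartiles on both sides of 0, only marginally. Feeding state stays open, because feeding that acts through the supply of fatty acids need not move these targets. A biological effect of ACC2 loss on this program is a hypothesis that these tables leave standing, but the Cre transgene has no control group here. The supply of fatty acids to the heart was not tested.

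Within 5 Mb of A1cf on chromosome 19, A1cf left out, Prkg1, Rnls and Lipo2 were called higher and Vldlr, Kcnv2 and Pank1 lower in iKO on chow, and the list of its neighbourhood lost its call with an estimated correlation (adjusted p = 0.505 on chow and 0.415 on HFD). That the transgene itself raises Lipo2 and Rnls is argued against by 2 WT HFD libraries, RT16 and RT18, with Lipo2 at 1.54 and 1.39 FPKM (0.06 to 0.12 in the other 8 WT libraries, 1.56 to 3.13 in iKO) and Rnls at 4.55 and 4.69, while A1cf is listed at 0 in both. A transgene insertion or a linked chromosome segment near A1cf stays open: genes called higher were 3 of 52 on chow against 40 of 12696 elsewhere (Fisher's exact p = 0.000704, two-sided) and 1 of 52 on HFD against 12 of 12696 (p = 0.0518), and genes called in either direction 6 of 52 against 129 of 12696 on chow (p = 1.72e-05) and 1 of 52 against 21 of 12696 on HFD (p = 0.0861). These counts leave out A1cf itself, which was listed between 0 and 0.01 FPKM in all WT libraries and between 0.11 and 1.31 in all iKO libraries. This separation by genotype goes with an insertion or segment at A1cf. An effect of ACC2 loss on A1cf would give it too, and no group carries the Cre alone. Reads shared within the Lipo family stay open too, with a log2 ratio of the summed family of 0.273 (SD 0.087) between iKO and WT on chow. On HFD the summed family was closer between genotypes, at 5.34 FPKM ± 0.518 (SD, n = 5) in iKO and 4.97 ± 0.311 in WT, where WT includes RT16 and RT18. A candidate explanation for Lipo2 and Rnls is a strain segment that segregates in the colony distal of A1cf, which no variant calls were at hand to test.

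Camera called the integrated and mitochondrial stress response upward in iKO on HFD (adjusted p = 0.158 with an estimated correlation). The genotype effect on the mean score was 0.252 on HFD (95% interval 0.15 to 0.354, exact p = 0.00794, the smallest possible with 5 libraries per group). On chow it was 0.094 (-0.009 to 0.196, exact p = 0.135), and the intervals overlap. The difference of 0.159 had a permutation p of 0.0242, but camera with an estimated correlation did not call the list for the interaction. The list was taken up for its call on HFD in these same libraries, so this p cannot decide whether Cre acts alike on both diets. As the source of the whole rise, a larger share of connective tissue is argued against by the iKO HFD libraries. RT11 and RT20, with fibroblast scores of -0.298 and -0.271 in the range of WT, had stress scores of 0.156 and 0.245. RT13, RT15 and RT17, with 0.456, 0.391 and 0.447, had 0.232, 0.222 and 0.082, against -0.099 to -0.008 in WT on HFD. A part of connective tissue in the rise stays open. With the fibroblast score as covariate the median was 0.145 (spread 0.067) instead of 0.18 (spread 0.076), and 1 member was called instead of 4. An effect of ACC2 loss and an effect of the Cre, alike on both diets or needing HFD, cannot be told apart without a group that carries the Cre alone.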

How the results depend on the processing

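The pseudocount, the residual component, the list tests under median-of-ratios scaling and the fits without RT4 and RT7 or without RT1 and RT4 were chosen after seeing the data. The count-based alternatives (quasi-likelihood fits with other size factors, a Wald test, voom and surrogate variables) were not run, because the values are FPKM. Quality weights were estimated in limma directly. No paired analysis was possible because the libraries of the groups share no numbers.

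Of 286 named results 224 were called. Calls were lost for 66 under median-of-ratios scaling, 62 under upper-quartile scaling, 54 with mitochondrial and haemoglobin genes removed, 35 without RT1 and RT4, 40 without RT4 and RT7, 9 with quality weights, 8 with a pseudocount of 0.1 and 2 with the residual component, and none reversed. Over all fits without 1 library, counted once per result and fit, calls were lost 412 times and gained 8 times, and 2620 pairs did not change. Called genes kept in every such fit numbered 79 of 136 (genotype on chow), 6 of 22 (genotype on HFD), 471 of 1027 (diet in WT), 657 of 1279 (diet in iKO) and 0 of 4 (interaction).

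Camera with an estimated correlation called 4, 1, 2, 5 and 1 lists for genotype on chow, genotype on HFD, diet in WT, diet in iKO and the interaction, and fry 6 on chow, 8 on HFD and 2 for the interaction. A fit of only the groups compared called 5 genes on HFD and 710 for diet in iKO. Diet in WT, diet in iKO and the interaction gave 338, 571 and 0 genes under median-of-ratios scaling, 353, 594 and 0 under upper-quartile scaling and 622, 830 and 0 without a filter (25052 genes tested), where genotype on HFD gave 7. With mitochondrial and haemoglobin genes removed, diet gave 310 genes in WT and 559 in iKO. With quality weights genotype on HFD gave 95 genes and diet in WT 2092. With the residual component, which left the fold changes as they were, genotype gave 417 genes on chow and 385 on HFD, and the interaction 2. Without RT1 and RT4 the counts were 87 for genotype on chow, 839 for diet in iKO and 0 for the interaction, and r was 0.539 for genotype and 0.558 for diet effects. Without RT4 and RT7 they were 74, 509 and 0, with 10 lists for the interaction and r of 0.541 and 0.567. With a minimum of 1 FPKM r was 0.627 and 0.633. With the WT HFD libraries split, the reversal medians were -0.106 for genes that rose and -0.041, reversed, for genes that fell. The cause was not tested.

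Without 1 library the called genes ranged from 92 to 151 (genotype on chow), 6 to 39 (genotype on HFD, lowest without RT12 and highest without RT11), 623 to 934 (diet in WT, lowest without RT3, and 660 without RT1), 872 to 1448 (diet in iKO) and 0 to 5 (interaction). The called lists ranged from 11 to 15, 15 to 20, 12 to 16, 8 to 10 and 6 to 8. The correlation r ranged from 0.534 without RT4 to 0.616 without RT7 for genotype effects and from 0.568 without RT4 to 0.616 without RT19 for diet effects. Acacb ranged from -2.01 to -1.97 on chow and from -1.78 to -1.69 on HFD. The reversal medians ranged from -0.175 to -0.127 for genes that rose and from -0.003, reversed without RT12 and RT15, to 0.016 for genes that fell. The estimated depth of 12.5 to 32 M reads limits low values such as those of A1cf, Asns and Mthfd2.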

Other observations

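The list tests under median-of-ratios scaling and the look at Lipo3 per library were chosen after the result was seen, and the other tests in this part before.

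In glucose uptake, glycolysis and pyruvate oxidation 7 of 38 genes fell and 1 rose on HFD in WT (18 and 1 adjusted over the list alone, median -0.11) and 7 fell and 1 rose in iKO (10 and 2 adjusted over the list alone, median -0.084). Camera did not call the list (adjusted p = 0.0553 in WT and 0.340 in iKO), fry gave adjusted p = 0.00192 and 0.0120, and under median-of-ratios scaling, where 1 fell and 3 rose in each genotype, the median was -0.013 in WT and 0.002 in iKO. Slc2a4, the insulin-responsive glucose transporter, fell by 0.26 in WT (SE 0.05, adjusted p = 0.00489) and by 0.28 in iKO (SE 0.05, adjusted p = 0.00191), and under median-of-ratios scaling its adjusted p was 0.211 and 0.0864. Slc2a1, the basal glucose transporter, fell by 0.45 in WT (SE 0.09, adjusted p = 0.00514) and had a log2 fold change of -0.27 in iKO (adjusted p = 0.0706). In mitophagy and autophagy 6 of 42 fell in WT on HFD (12 adjusted over the list alone, median -0.098) and 2 in iKO (2 adjusted over the list alone, median -0.058), and camera did not call the list (adjusted p = 0.0574 and 0.721), while fry did (0.00119 and 0.0311). Its medians turned to 0.004 and 0.019 under median-of-ratios scaling.

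Lists that camera called in no comparison are given for the diet in WT. The median was -0.078 for mitochondrial fission and fusion (adjusted p = 0.672), -0.10 for mitochondrial biogenesis regulators (0.689), -0.20 for inflammation (0.843), -0.12 for antioxidant and NRF2 targets (0.689), -0.078 for p53 targets and DNA damage (0.180) and -0.081 for the circadian clock (0.843). It was -0.41 for atrial cardiomyocyte markers (0.580), -0.090 for endothelial markers (0.580), -0.12 for smooth muscle and pericyte markers (0.541) and -0.068 for Schwann cell and neuronal markers (0.180). The medians for fission and fusion, p53 targets, the circadian clock and endothelial markers turned to 0.023, 0.002, 0.002 and 0.011 under median-of-ratios scaling. Camera pointed up although the median was below 0 for antioxidant and NRF2 targets (mean -0.031), p53 targets (mean 0.012), endothelial markers and Schwann cell and neuronal markers. Of the members, 6 fell and 4 rose among antioxidant and NRF2 targets (12 and 4 adjusted over the list alone), 2 fell and 1 rose among biogenesis regulators (3 and 1), 2 fell among p53 targets (2, with 1 higher), 2 among the circadian clock (4) and 1 among atrial markers (1). Fry called fission and fusion (adjusted p = 0.0321), biogenesis regulators (0.0141), the circadian clock (0.0321) and smooth muscle and pericyte markers (0.0141), all down.

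The marker lists too small to test had these medians for genotype on chow, genotype on HFD, diet in WT and diet in iKO. They were -0.099, -0.23, -0.33 and 0.044 for white adipocyte markers (1 fell on chow and 1 rose with the diet in iKO), and -0.12, 0.036, -0.068 and -0.010 for brown adipocyte markers (1 rose with the diet in iKO). They were 0.20, 0.17, -0.21 and -0.093 for lymphocyte markers and -0.071, -0.11, 0.083 and 0.048 for the 1 gene of mesothelial and epicardial markers, with no member called. No gene of lung epithelium markers passed the filter.

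Lipo3, which overlaps Lipo2, stood between 4.22 and 4.81 FPKM in 8 WT libraries, at 3.51 and 3.19 in RT16 and RT18, and between 1.49 and 3.61 in the 10 iKO libraries. It did not pass the test between genotypes on chow (log2 fold change -0.61, adjusted p = 0.106) or on HFD (-0.49, adjusted p = 0.225).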
